A study of Mus musculus with 3 samples.

How the data were processed

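The series holds 3 one-colour Affymetrix arrays of mouse neural retina, whose sample titles carry the name of the U74Av2 array. Per the labels, the mice were Rp1 knockouts on a mixed 129/SvEv and C57BL/6 background, were killed at postnatal day 21, and gave their retinas between 1 and 2 pm. Each RNA was a pool of the neural retinas of 3 to 4 mice. The 3 samples form 1 group. No control or wild-type group was analysed here, so no contrast between groups was made and no gene was tested between conditions. The replicate numbers 1 to 3 only name the samples. The 3 pools are separate samples per the labels. Every p-value and every percentile among random lists below describes these 3 arrays alone, with genes and not pools as the units.

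The deposited table gives 1 linear intensity per probe set and array, for 12488 probe sets, with no missing value and none at or below 0. How the authors computed these intensities (software, background correction, scaling target) is not given in the sources used here. In the deposited intensities the mean after trimming 2% at each end over all probe sets was 500.2, 500.3 and 500.2 in replicates 1, 2 and 3, so the arrays share a common scale as deposited. No detection calls were part of the table used here.

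Before log2 transformation, each array was multiplied by a single factor that set its 2% trimmed mean over the 12422 probe sets that are not controls to the mean of the 3 arrays. The factors were 0.998, 1.00 and 1.00. Values below the 5th percentile of an array were set to that percentile for log2 values only. A probe set counted as above background on an array when its signal exceeded the 95th percentile of the 19 control probe sets for bacterial and yeast transcripts. That limit was 160.3, 80.7 and 107.1 for replicates 1, 2 and 3. The limit describes signal and does not stand for a detection test of the array software. The number of arrays limits the precision of every value.

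Gene symbols came from the array's platform annotation. In it, 10833 probe sets carried 1 symbol, 396 carried several and 1193 carried none, and only the first kind named a gene. Of the resulting 8251 genes, 8241 had a symbol in the mouse gene table of assembly GRCm38.p6, which was used for names alone. For the 2073 genes with more than 1 probe set, a probe set with a plain suffix was preferred, and among these the one with the highest mean. No coordinates are printed, because the table used here names no genome build. Gapdh appears on the array as a control and was left out of the gene lists.

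Before the data were examined, 25 gene lists were fixed (retinal cell types, neighbouring eye tissues, blood, stress, clock, proliferation and metabolic genes), together with the rule for named genes. The named genes were the first 4 of each list with a probe set of their own, the 10 genes with the largest range over the 3 samples among those above background on all 3 arrays, and up to 4 members of each list whose spread lay outside the percentiles below. Any other gene named was chosen after its values were seen, and is said to be so. The share of members above background on all 3 arrays was set against that of all other genes with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over the lists. The median SD of a list on the log2 scale was placed among 10000 random lists of the same size, matched on mean level in 20 bins. The median deviation of each sample from the mean of the other 2 was placed among matched random lists in the same way. The last 2 comparisons used lists with at least 3 genes above background on all 3 arrays, and a list was called where it lay outside the central 95% of the random lists. The p-values of spread are gene permutations of this kind, in which genes and not samples were drawn. Genes of a list are not independent of each other.

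The list and range computations were tested on simulated data for the 5006 genes above background on all 3 arrays, with the median SD of each level as noise. A range of 1 or more on the log2 scale was reached by 15.0% of unchanged genes, by 64% of genes changed 2-fold in 1 sample and by 100% of those changed 4-fold. Of unchanged lists of 10 genes, 4.33% lay outside the percentiles for deviation and 5% for spread. A deviation of 0.5 in 1 sample was found in 86% of such lists and a deviation of 1 in 100%. The simulated noise was independent between genes and alike in the 3 samples, unlike the data. These rates therefore check the computation and do not give the share of false calls among real genes or lists.

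Alternatives to the background limit, array scaling, floor, pseudocount, range threshold and choice of probe set were tried, and each sample was left out in turn. Scaling to a common median, or quantile normalization, moved the median log2 signal by -0.22 in replicate 1, 0.23 in replicate 2 and 0.02 in replicate 3, so sample deviations are given beside those of matched lists. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.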

Results

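The transcript levels of neural retina from Rp1 knockout mice were measured on 3 arrays at postnatal day 21, 1 array per pool of retinas. Rp1 encodes a microtubule-associated protein of the photoreceptor axoneme and outer segment. Signals were above background on all 3 arrays for 6752 of the 12422 probe sets (54.4%), on 1 or 2 arrays for 3081 and on no array for 2589. By array, 7921 probe sets were above background in replicate 1, 8624 in replicate 2 and 8442 in replicate 3. At the level of genes, 5006 of 8251 were above background on all 3 arrays. Values below are mean scaled signals ± SD over the 3 pools (n = 3), and signals of different genes are not set against each other because probe sets differ in response.

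The targeted gene could not be followed. No probe set carried the symbol Rp1 in the annotation used, so the gene was not analysed here and the knockout label stands on the submitters' description alone.

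Transcripts of rod photoreceptors were detected throughout. All 12 measured genes of rod phototransduction were above background on all 3 arrays, against 60.6% of other genes (two-sided Fisher's exact test, adjusted p = 0.041). Gnat1, the rod transducin alpha subunit, had a signal of 39398 ± 10959. The rod phosphodiesterase subunits gave 12193 ± 2796 for Pde6b, 2536 ± 887 for Pde6a and 23286 ± 4887 for Pde6g. Of the outer segment and photoreceptor cilium genes, 9 of 10 were above background (adjusted Fisher's exact p = 0.23). The disc rim proteins Prph2 and Rom1 gave 2700 ± 1537 and 5084 ± 1575, and the outer segment proteins Abca4 and Prom1 gave 6602 ± 78.7 and 10082 ± 1938. Without replicate 1 the adjusted Fisher's exact p of the rod list was 0.19, and with the 40th percentile of each array or the median of the control probe sets as limit it was 0.10 or 1.

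Cone markers were above background for 5 of 6 genes (adjusted Fisher's exact p = 0.54). The cone opsins Opn1sw and Opn1mw gave 3403 ± 1064 and 1920 ± 694, and the cone transducin Gnat2 gave 2318 ± 633. The cone channel subunit Cnga3, at 50.4 on average, was above background on no array. Among photoreceptor transcription factors, 6 of 7 were above background (adjusted Fisher's exact p = 0.38). Crx gave 4896 ± 804 and Neurod1 gave 5036 ± 1726. Nrl, which directs rod fate, gave 890 ± 512, Thrb gave 350 ± 220 and Mef2c gave 334 ± 249, each with its highest signal in replicate 1, although of the other 3 probe sets of Mef2c 1 was lowest there, at 28.7 against 118 and 152.

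The photoreceptor transcription factors spread more between pools than matched lists, with a median SD of 0.63 against 0.36 on the log2 scale (percentile 99.03, adjusted gene-permutation p = 0.11). Their median deviation was 0.63 in replicate 1 against -0.13 in matched lists (percentile 99.6) and -0.54 in replicate 2 against 0.16 (percentile 0.16), although in replicate 1 only 3 of the 6 genes lay higher. Rod genes had a spread at the 81.6th percentile, outer segment genes at the 12.5th and cone genes at the 95.2nd. In replicate 3 rod genes deviated by -0.28 against -0.02 in matched lists (percentile 0.79), with 8 of 12 genes lower. In replicate 2 cone genes deviated by 0.72 against 0.31 (percentile 99.4), with 4 of 5 genes higher. The spread of the transcription factors lay at the 86.3rd percentile without replicate 1, at the 89.6th without replicate 2 and at the 46.4th with the mean of all probe sets of a gene, where their deviations lay inside the limits too, at percentile 79.56 in replicate 1 and 20.96 in replicate 2, and the spread was at 89.96 with arrays scaled to a common median and 94.58 after quantile normalization. The rod deviation in replicate 3 moved to the 55.9th percentile under quantile normalization, to 2.64 with the 40th percentile of each array as limit and to 4.44 with the mean of all probe sets, the spread of rod genes without replicate 1 lay at the 99.3rd, and that of cone genes at the 99.1st without replicate 3 and at 98.19 with arrays scaled to a common median.

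Inner retinal neurons were represented on all arrays. Bipolar markers were above background for 3 of 4 genes (adjusted Fisher's exact p = 1). Trpm1, the channel of ON bipolar cells, gave 754 ± 123, Pcp2 gave 388 ± 156 (2239 ± 396 at another probe set) and Car8 gave 863 ± 405. Prkca, a rod bipolar marker, was 67.6 in replicate 1, below the limit there, and 526 and 431 in replicates 2 and 3, at least 3.28-fold higher in replicate 2 than in replicate 1. Amacrine and horizontal cell markers were above background for 10 of 14 genes (adjusted Fisher's exact p = 0.67). Gad1, a GABA-synthesising enzyme, gave 4846 ± 726, the glycine transporter Slc6a9 gave 2445 ± 728 and the horizontal cell marker Calb1 gave 821 ± 132, while Gad2 (97.8 ± 19.7) was above background on 1 array.

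All 8 measured ganglion cell markers were above background (adjusted Fisher's exact p = 0.11). The neurofilament genes gave 1517 ± 51.6 for Nefl, 350 ± 237 for Nefm and 1179 ± 265 for Nefh, and Thy1 gave 1859 ± 473. Ganglion cell genes deviated by 0.49 in replicate 1 against -0.02 in matched lists (percentile 98.9, 6 of 8 genes higher) and by -0.38 in replicate 3 against -0.01 (percentile 1.5, 7 of 8 genes lower). With the mean of all probe sets these moved to the 90.7th and 10.5th percentiles, and the latter was 3.25 with the highest control and 2.52 with the 40th percentile of each array as limit. Synaptic genes were above background for 8 of 9 (adjusted Fisher's exact p = 0.23), with Ctbp2, the source of the ribbon protein RIBEYE, at 3702 ± 215, Syp at 1503 ± 238, Snap25 at 11149 ± 1894, Syt1 at 4934 ± 1682 and Dlg4 at 680 ± 193. Synaptic genes spread less than matched lists, with a median SD of 0.21 against 0.33 (percentile 2.32, adjusted gene-permutation p = 0.17). That percentile was 5.18 without replicate 1, 47.8 without replicate 2 and 79.9 after quantile normalization, and it lay above the 2.5th in 7 further alternatives, while scaling to a common median gave 0.06. The spread of bipolar, amacrine and horizontal, and ganglion cell markers lay at the 86.1st, 60.6th and 48.7th percentiles.

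All 10 measured Müller glia markers were above background (adjusted Fisher's exact p = 0.051). Glul, the glutamine synthetase of Müller cells, gave 2442 ± 1091, the retinaldehyde-binding protein gene Rlbp1 gave 3470 ± 753, the water channel Aqp4 gave 1131 ± 417, Clu gave 7128 ± 3022, Car14 gave 2019 ± 787 and Vim gave 246 ± 202. Their median SD was 0.52 against 0.34 in matched lists (percentile 99.3, adjusted gene-permutation p = 0.10), and 58.7 and 86.6 were the percentiles without replicate 1 and without replicate 3. Without replicate 2 it was 99.81 (adjusted gene-permutation p = 0.044). The Müller spread also lay inside the percentiles in 5 of the alternatives with all samples, between the 89.9th and the 94.6th. The members did not move together, since Glul and Vim had their highest signals in replicate 1 and Clu, Car14 and Aqp4 their lowest. A further probe set did likewise for Clu and Aqp4, but that of Glul gave 1828, 457 and 1873 in replicates 1, 2 and 3.

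Among genes of the retinal injury response, 8 of 13 were above background (adjusted Fisher's exact p = 1). Gfap, the intermediate filament of astrocytes and reactive Müller cells, gave 247 ± 85.5 at one probe set and 665 ± 111 at another. Cebpd gave 1252 ± 489, Fgf2 (48.9 ± 19.7) was above background on no array, and Edn2, the gene of a photoreceptor-derived injury signal, was 143 in replicate 1, below the limit there, and 493 and 481 in the other samples. Microglia and immune markers were above background for 6 of 14 genes (adjusted Fisher's exact p = 0.35), or 7 where any probe set of a gene counted. C1qa gave 616 ± 136 and Csf1r gave 313 ± 47.1, with 1432, 248 and 223 in replicates 1, 2 and 3 at another Csf1r probe set, while Cd68 (173 ± 105) was below the limit in replicate 1 and Aif1 (80.6 ± 47.8) was above it only in replicate 3. The spread of injury and immune genes lay at the 78.2nd and 53.3rd percentiles, and that of immune genes at the 99.9th with the highest-mean probe set of each gene (adjusted gene-permutation p = 0.028).

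Genes of pigmented cells differed between the pools. Dct, an enzyme of melanin synthesis, had a signal of 765 in replicate 1, 5724 in replicate 2 and 3742 in replicate 3, a 7.49-fold range. Pmel, the melanosome matrix protein gene, followed with 454, 4105 and 2610, a 9.04-fold range. Tyrp1 was 63.2 in replicate 1, below background, and 1434 and 997 in the other samples, so that replicate 2 was at least 8.94-fold higher at this probe set. Other Tyrp1 probe sets gave 98.9, 519 and 574, and 30.4, 206 and 167, also below background in replicate 1, while a further one was below it on all arrays. The retinol dehydrogenase gene Rdh5 was likewise below background in replicate 1, at 56.7, and reached 587 and 316, at least 3.66-fold higher in replicate 2. Ttr, at 678 ± 189, did not show this pattern.

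Of the 7 measured pigment epithelium and melanocyte markers, 3 were above background on all 3 arrays (adjusted Fisher's exact p = 0.56). The median SD of these 3 genes, 1.53 against 0.32, exceeded that of all 10000 matched lists (p = 0.0002, the smallest that the random lists can give, adjusted gene-permutation p = 0.0044). Their median deviation was -2.60 in replicate 1, 1.76 in replicate 2 and 0.84 in replicate 3 (percentiles 0, 100 and 99.5). The 3 genes were Dct, Pmel and Ttr, with SDs of 1.53, 1.68 and 0.38 on the log2 scale. The median SD is therefore that of Dct alone, and Ttr did not share the wide spread. The 3 deviations of a gene cancel out, so the values above the other samples in replicates 2 and 3 partly restate the low replicate 1. Dct and Pmel were lower in replicate 3 than in replicate 2. Without replicate 1 the percentile of the spread was 97.4, just inside the limits, with an adjusted gene-permutation p of 0.21.

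**Figure D1:**
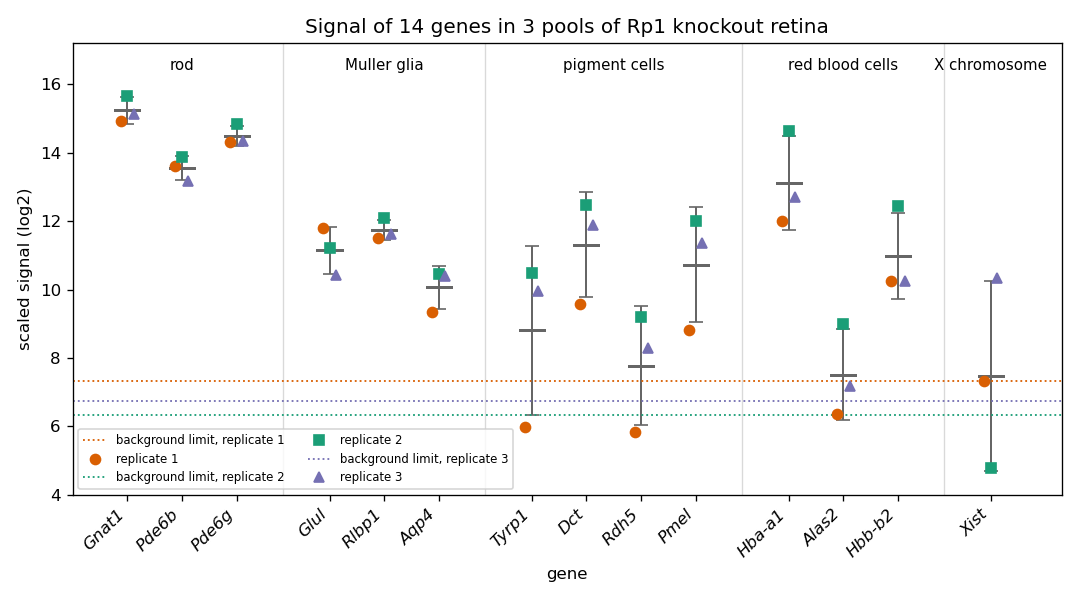
Scaled signal on a log2 axis of 14 genes of rods, Muller glia, pigmented cells, red blood cells and the X chromosome in each of the 3 pools. Symbols are the samples, grey bars the mean ± SD of the log2 values (n = 3) and dotted lines the background limit of each array.

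Several red blood cell transcripts were highest in replicate 2. Hba-a1, an alpha-globin gene, was 4077, 25566 and 6661 in replicates 1, 2 and 3, and the beta-globin gene Hbb-b2 was 1218, 5536 and 1207. Globin genes are near-identical copies, so these probe sets may take signal from several of them, and of 2 probe sets listed for the same 4 beta-globin genes 1 gave 5848, 33901 and 7823, while the other was below background on all arrays. Alas2, the erythroid enzyme of haem synthesis, was below background at 82.8 in replicate 1, and was 505 and 145 in the other samples. Slc4a1 (154 ± 74.9) did not follow, being highest in replicate 3. Of the 6 measured blood genes 2 were above background on all arrays (adjusted Fisher's exact p = 0.37), too few for the comparison of spread. In a setting chosen after the data were seen, which set all values below 160.3 to that level, 5 blood genes had a spread above all 10000 matched lists.

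Lens transcripts were present in all pools, with 10 of 11 lens genes above background (adjusted Fisher's exact p = 0.21), or 11 where any probe set of a gene counted. The crystallin genes Cryaa, Cryba1, Crygb and Crygs gave 49258 ± 11618, 40752 ± 7272, 20190 ± 6778 and 37901 ± 13640, and the lens membrane gene Mip gave 1584 ± 424. Crygd (630 ± 579), Gja3 (257 ± 145) and Bfsp1 (784 ± 337) were highest in replicate 1, but another Crygd probe set gave 41532, 52417 and 27299. The retina itself also expresses some crystallins, so these signals need not come from lens. The median SD of lens genes was 0.50 against 0.35 (percentile 98.2, adjusted gene-permutation p = 0.16), and in replicate 3 they deviated by -0.41 against -0.03 (percentile 0.18, 8 of 10 genes lower). The percentile of the spread was 94.4, 92.3 and 75.7 without replicates 1, 2 and 3 in turn, and that of the deviation was 10.8 after quantile normalization. The lens spread also lay inside the percentiles in 6 alternatives with all samples, between the 91.1st and the 96.1st.

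Vascular markers were above background for 4 of 10 genes (adjusted Fisher's exact p = 0.37), with Pecam1 at 426 ± 180, Kdr at 718 ± 166 and Cldn5 at 407 ± 73.8, while Cdh5 (134 ± 75.7) was below the limit in replicate 3. Cornea and connective tissue markers were above background for 5 of 10 (adjusted Fisher's exact p = 0.63), with Krt12 at 336 ± 116, Col1a1 at 578 ± 181, Lum at 201 ± 39.7 and Aldh3a1 (229 ± 119) below the limit in replicate 1. Skeletal muscle markers were above background for 2 of 10 (adjusted Fisher's exact p = 0.088, and 0.043 with the highest control probe set as limit). Mylpf gave 195 ± 34.6, Acta1 (150 ± 81.2) and Ckm (212 ± 123) were below the limit in replicate 1, and Tnnt3 (132 ± 137) was above it in replicate 1 alone. Vascular genes and connective tissue genes had a spread at the 79.3rd and 69.0th percentiles. Named after their values were seen, Dcn of connective tissue was 23.1, 602 and 648 in replicates 1, 2 and 3, and Acta2 of smooth muscle was 55.5, 722 and 734, so that both were below background in replicate 1.

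Xist, the non-coding RNA of the inactive X chromosome, was 159 in replicate 1 and 27.6 in replicate 2, below background in both, and 1290 in replicate 3. Replicate 3 was thus at least 8.05-fold and at least 15.99-fold above them. The Y-linked genes Eif2s3y (649 ± 81.1) and Uty (144 ± 35.5) were above background on all arrays, and Kdm5d (91.3 ± 19.7) in replicate 3 alone, at 112 against a limit of 107.1. Of 4 sex-linked genes 2 were above background on all arrays (adjusted Fisher's exact p = 0.71), and the sex of the pooled mice is not given in the labels.

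Clock genes were above background for 11 of 13 (adjusted Fisher's exact p = 0.23), with a spread at the 38.4th percentile. In retinas all taken in the early afternoon, Per1 gave 492 ± 66.6, Dbp gave 1056 ± 239, Nr1d1 gave 1031 ± 190, and Per2 (136 ± 38.1) was below the limit in replicate 3. Immediate early genes were above background for 10 of 12 (adjusted Fisher's exact p = 0.30, and 0.033 without replicate 3). Fos gave 781 ± 15.3, Junb 694 ± 229, Egr1 412 ± 264 and Nr4a1 571 ± 149, while a further probe set of Fos and one of Egr1 were below background on all arrays. Immediate early genes deviated by 0.60 in replicate 1 against 0.10 in matched lists (percentile 98.7, 8 of 10 genes higher), and this became 94.3 when arrays were scaled to a common median, 95.6 with the mean of all probe sets and 97.26 where values below 160.3 were set to that level. Their spread lay at the 91.5th percentile, and at the 98.8th without replicate 3. Heat shock genes were above background for 8 of 9 (adjusted Fisher's exact p = 0.23), with Hspa1a at 1078 ± 245, Hspa1b at 603 ± 130, Hspa8 at 5139 ± 1119 and Hsph1 at 904 ± 138, and a spread at the 65.1st percentile. Proliferation and progenitor genes were above background for 5 of 12 (adjusted Fisher's exact p = 0.37, spread at the 49.2nd percentile). Pcna gave 837 ± 137 and Ccnd1 481 ± 119, Top2a (28.7 ± 31.9) was above background on no array, and Mki67 was above it at its chosen probe set in replicate 1 alone, with 246, while another probe set gave 118, 96.7 and 259, below the limit in replicate 1 and above it in the other samples.

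Genes of energy metabolism were detected more often than other genes. All 13 measured genes of glycolysis were above background (adjusted Fisher's exact p = 0.033), with the hexokinases Hk1 and Hk2 at 3826 ± 1462 and 2936 ± 372, Pkm at 17381 ± 1909 and Ldha at 13457 ± 3097. Another Hk2 probe set was below background on all arrays. Of 72 genes of oxidative phosphorylation, 61 were above background, 84.7% against 60.5% of other genes (adjusted Fisher's exact p = 0.00037). Uqcrc1 gave 2804 ± 389, Atp5a1 6585 ± 1505, Atp5c1 2577 ± 604 and Cox4i1 273 ± 105. Without replicate 1 the adjusted Fisher's exact p was 0.17 for glycolysis and 0.00020 for oxidative phosphorylation, and with the median of the control probe sets as limit it was 1 and 0.25, so that neither list passed. Ribosomal protein genes were above background for 24 of 35 (adjusted Fisher's exact p = 0.54), with Rplp0 at 8598 ± 2948, Rps3 at 6933 ± 2113, Rpl10a at 4481 ± 1160 and Rpl13a at 784 ± 218.

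Oxidative phosphorylation genes also differed between pools, with a median SD of 0.42 against 0.33 (percentile 99.8, adjusted gene-permutation p = 0.040). In replicate 2 they deviated by 0.49 against 0.20 in matched lists, above all 10000 of them, with 52 of 61 genes higher, and in replicate 3 by -0.15 against -0.00 (percentile 0.31, 42 of 61 lower). Uqcr11 was 473, 2050 and 1199 in replicates 1, 2 and 3, Atp5e was 504, 1755 and 983, and Ndufc1 was 989, 2860 and 1256, whereas Ndufa6 was 1399, 622 and 263. Ribosomal protein genes deviated by 0.57 in replicate 2 against 0.32 (percentile 99.95, 18 of 24 higher), and glycolysis genes by -0.28 in replicate 3 against -0.02 (percentile 0.50, 11 of 13 lower). The spread of glycolysis genes lay at the 30.9th percentile and that of ribosomal protein genes at the 93.2nd. The adjusted gene-permutation p of the oxidative phosphorylation spread was over 0.05 in 6 alternatives with all samples (0.064 to 0.47) and without replicate 3 (0.058). Without replicate 2 the percentile of that spread was 49.2, and without replicate 1 those of glycolysis and ribosomal protein genes were 98.1 and 99.8. The ribosomal spread also lay outside the limits with arrays scaled to a common median (98.71) and with the mean of all probe sets (98.23).

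**Figure D2:**
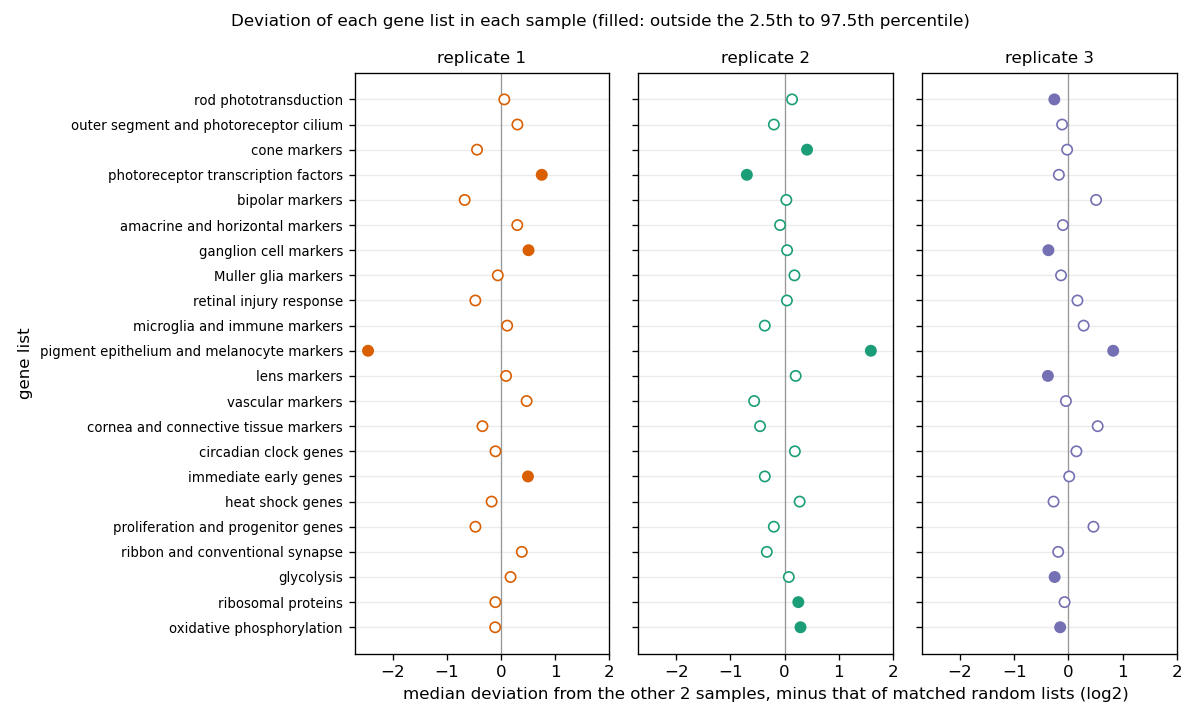
Median deviation of each of 22 gene lists in each sample from the mean of the other 2, minus the median of level-matched random lists, in log2 units. Filled points lie outside the central 95% of 10000 random lists, which holds for 4 lists in replicate 1, 5 in replicate 2 and 6 in replicate 3, and the pigment list lies farthest from 0 in every panel.

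Over all 22 lists with enough genes, 6 had a spread outside the percentiles, and 2 of them had an adjusted gene-permutation p under 0.05. These were the pigment list, which rested on 3 genes, and the oxidative phosphorylation list, which passed narrowly. Of the 66 pairs of list and sample, 15 deviations lay outside the percentiles, where chance alone would give 3.3 if pairs were independent, which they are not. All other deviations lay within the percentiles in this setting, but 16 of them lay outside in at least 1 alternative. Among these were connective tissue genes in replicate 3 (97.85 to 99.7 in 4 alternatives), synaptic genes in replicate 1 (97.97 to 99.79 in 4), bipolar genes in replicate 1 (1.49 to 2.43 in 3), and injury genes in replicate 1 (0.71 to 2.32 in 3) and replicate 3 (98.77 to 99.31 in 3).

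Replicates 2 and 3 resembled each other more than either resembled replicate 1. Spearman correlations across probe sets, which are not independent replicates, were 0.938 between replicates 2 and 3, 0.827 between 1 and 2, and 0.821 between 1 and 3. Signals lay at least 2-fold apart for 468, 1450 and 1204 of the 6752 probe sets above background in these pairs. No pair shared more than 9 identical values. The median SD over the 3 samples was 0.38 on the log2 scale, and 2067 probe sets (30.6%) had a range of 1 or more. Replicate 1 lay farthest from the mean of the others in 1281 of these, higher in 832 and lower in 449, against 464 for replicate 2 and 322 for replicate 3. Without replicate 1 the count of probe sets with such a range was 600, without replicate 2 it was 1293, and after quantile normalization it was 1864. Deposited intensities spanned a narrower range on array 1, with a 5th percentile of 29 against 9.7 and 12.7 on arrays 2 and 3. The 95th percentile was 2046 against 2561 and 2405.

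The 10 genes with the largest ranges fell into 2 kinds. In Rpl32 (1904, 101 and 256 in replicates 1, 2 and 3), Chaf1b (1275, 85.1 and 343), Serpina6 (1639, 113 and 189), Pax4 (1359, 107 and 394), Mrm3 (1333, 115 and 274) and Igfbp6 (967, 83.9 and 127), replicate 1 was highest and another sample lay close to its background limit. In Ptgds, the prostaglandin D synthase gene (889, 12449 and 6736), Inpp4a (523, 2614 and 6836), Serpina3n, an acute-phase gene induced in reactive glia (223, 1437 and 2588), and Pigt (171, 619 and 1647), replicate 1 was lowest. For Serpina3n and Pigt the signal in replicate 1 was likewise not far above its background limit of 160.3. The Rpl32, Inpp4a and Ptgds values rest on probe sets whose suffix marks a relaxed probe choice. The other 2 Ptgds probe sets also had their lowest signals in replicate 1 (2257 against 8353 and 4569, and 1665 against 8114 and 4901), while a further probe set gave 215, 89.4 and 88.5 for Mrm3 and 105, 47.9 and 124 for Serpina6, the latter not highest in replicate 1.

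The 3'/5' ratio of the actin control was 1.31, 1.499 and 1.47 in replicates 1, 2 and 3, and that of the Gapdh control was 0.898, 0.929 and 0.845. Where genes had 2 plain probe sets above background on all arrays, the deviations of a sample at the 2 probe sets hardly went together. Across 321 such genes, which are not independent replicates, Pearson's r was -0.011 for replicate 1, 0.088 for replicate 2 and 0.039 for replicate 3, so a value of a single gene in a single sample may reflect its probe set.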

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

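The alternative that set low values to 160.3 and kept genes above it on at least 1 array, and the count of a gene as above background where any of its probe sets is, were chosen after the data were seen. Probe sets above background on all 3 arrays numbered between 6034 and 9986 under the other limits and scalings, and those above it on both remaining arrays between 6978 and 7865 when each sample was left out, all within 1.5 times the reported count. The Spearman and Pearson correlations of replicates 2 and 3 stayed above those with replicate 1 under every floor, pseudocount and filter tried. A single factor per array cannot change these correlations, the control ratios or the count of probe sets above background, so those scalings test none of them. Quantile normalization cannot change a Spearman correlation. It gave Pearson correlations of 0.827 and 0.821 with replicate 1 and 0.931 between replicates 2 and 3, and moved the mean control ratios by less than their SD. Deviations of lists outside the percentiles numbered between 15 and 20 where 66 pairs were tested, 14 and 20 of 69 with the mean of all probe sets and the highest-mean probe set, 20 of 75 with the median of the control probe sets as limit, and 22 of 75 where low values were set to 160.3. Lists above background more or less often than other genes numbered 1 to 4 when each sample was left out in turn. In the reported setting 6 lists had an unadjusted p under 0.05 by Fisher's exact test, among them skeletal muscle markers, which were above background less often. When the median of the control probe sets was the limit, 0 of 25 lists passed after adjustment and 3 had such an unadjusted p, since most genes then pass. Probe sets with a range of 1 or more numbered 4594 with that lower limit and 6826 with no limit, as more dim probe sets enter, 743 with a range of 1.5 or more, and 600 to 1637 when each sample was left out, the fewest without replicate 1. Lists with a spread outside the percentiles numbered 2 after quantile normalization, 3 with the 40th percentile of the array as limit, and 2 to 6 when each sample was left out. The pigment list had a spread percentile of 97.36 to 100 when each sample was left out. Lists called in neither setting also changed sides, such as the spread of immune genes, at 53.32 and at 35.96 where low values were set to 160.3. Among results called in the reported setting or the alternative, sides changed in 5 cases, whose cause was not tested. These were the spread of synaptic genes (percentile 79.86) and the deviation of rod genes in replicate 3 (percentile 55.87) after quantile normalization, the spread of photoreceptor transcription factors with the mean of all probe sets (46.43), and 2 spreads with a sample left out, glycolysis without replicate 1 (98.12) and oxidative phosphorylation without replicate 2 (49.25). The pigment deviation in replicate 1 stayed below the 2.5th percentile under all alternatives run. The alternatives planned for Rp1 gave no value, as no probe set carried its symbol. Because the limit of array 1 (160.3) is higher than those of arrays 2 and 3 (80.7 and 107.1), a low signal is bounded less tightly in replicate 1.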

Other observations

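Further gene groups were looked at in lists written after some of their values had been seen. The tests of degraded RNA, of a compressed scale and of the sex of the mice were also chosen after the result was seen, as were the level of 160.3 below which values were set to that level and the comparison with the 75 genes that deviated most. For 5 explanations the rule written before the test gave a verdict, and the verdict was withdrawn after the value was seen, as stated for each below.

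For the lists of this paragraph, spread and deviation were taken with values below 160.3 set to that level. Genes above that level on at least 1 array were used for them. Metallothionein and antioxidant genes were above background for 12 of 13 (two-sided Fisher's exact test, adjusted p = 0.15). All 13 entered the comparison of spread. They spread more than matched lists, with a median SD of 0.47 against 0.32 on the log2 scale (percentile 98.7, adjusted gene-permutation p = 0.19). Mt1 was 1035, 2370 and 2071 in replicates 1, 2 and 3 and Mt2 was 1911, 2997 and 3341, whereas Mt3 was 2170, 1184 and 1110. Genes of intraflagellar transport and tubulin were above background for 10 of 11 (adjusted Fisher's exact p = 0.21, spread at the 69.1st percentile), among them Ift88 at 2284 ± 467 (SD, n = 3) and Ift20 at 770 ± 166. Glutamate and GABA receptor genes were above background for 6 of 10 (adjusted Fisher's exact p = 0.48 or more for this and the lists that follow, spread at the 59.5th percentile), and neuropeptide genes for 7 of 12 (86.3rd percentile), with Npy at 505 ± 138, Vip at 311 ± 147 and Penk at 1014 ± 167. Interferon and antigen presentation genes were above background for 5 of 12 (85.5th percentile), apoptosis genes for 5 of 9 (86.8th percentile) and myelin genes for 3 of 8 (17.6th percentile). A probe set of Mbp gave 990, 107 and 141 in replicates 1, 2 and 3, while another gave 322, 343 and 557. None of the 21 deviations of these lists in a single sample lay outside the central 95% of matched lists.

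Replicate 1 stood apart from the other samples. Degraded RNA in that pool is argued against by its actin 3'/5' ratio of 1.31, the lowest of the 3, and its Gapdh ratio of 0.898, below that of replicate 2, as far as these control transcripts tell. Carried-over eye tissue stays open: the gap between the correlation of replicates 2 and 3 and those with replicate 1 shrank by 1.13% without 75 genes of neighbouring tissues, but leaving out the 75 genes that deviated most in replicate 1 lowered it by only 11.2%, short of the 25% the written rule asked for, and its verdict against carry-over was withdrawn. Noise in dim probe sets stays open, since the gap was 0.148 in the 3106 brightest probe sets against 0.114 over all, but the narrower range also lowered the correlation of replicates 2 and 3 to 0.844, so the verdict against noise that the written rule gave was withdrawn. By rank, replicate 1 stood apart among these bright probe sets too, with correlations of 0.701 and 0.691 against 0.844. Median absolute log2 differences, looked at afterwards, were 0.437 and 0.398 with replicate 1 against 0.310 between replicates 2 and 3 in the brightest 25% of probe sets, and 0.622 and 0.5998 against 0.373 in the next 25%. Such differences also hold shifts in level between arrays, which were not removed, so they cannot show how far disagreement alone set replicate 1 apart. Errors of single probe sets on array 1 may contribute, with r = -0.0113 between its deviations at 2 probe sets of a gene, yet the other samples gave 0.0875 and 0.0389 and the mean levels of the 2 probe sets correlated at 0.196, so the verdict for such errors that the written rule gave was withdrawn. No biological explanation was tested, because the labels describe the 3 pools alike, but the title of replicate 1 differs from the others in format and has a number farther from theirs, so a difference of batch was not tested and stays open.

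Pigment genes were low in replicate 1, with all 7 measured genes below the mean of the other samples once values under 160.3 were set to that level (median deviation -1.43). That count was partly fixed by the setting. A gene under 160.3 in replicate 1, such as Tyrp1 or Rdh5, could only come out lower there. Of the 3 genes above background on all arrays, Dct and Pmel were lowest in replicate 1 and Ttr was not. Intensities did span a narrower range on array 1. For the pigment list alone, a compressed scale is argued against as the explanation. Its median deviation of -1.43 compares with -0.16 in lists matched on the level in the other samples (percentile 0). The list had been singled out for its low rank in these same arrays, so the percentile adds no independent evidence and only the size of the difference bears on the scale. Less pigment epithelium and choroid carried into pool 1, and pigmentation alleles that segregate on the mixed background, are both possible explanations that 27 further genes of those tissues outside melanin synthesis were meant to separate. Their median deviation in replicate 1 was 0.0569 at the 70.35th percentile, but 10 of 19 genes were higher and 9 lower, and many are also made by retinal cells. The written rule counted such a median for the alleles and against carried-over tissue, and both verdicts were withdrawn because the genes went both ways.

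Xist was high in replicate 3 alone, which may reflect more female mice in pool 3. The Y-linked gene Eif2s3y, however, was 1.05 times the mean of the other samples there, and Uty (184, 117 and 131 in replicates 1, 2 and 3) was close to the limits. Kdm5d (88.8, 73.0 and 112) was highest in replicate 3 and above background there alone, but only just over the limit. The Eif2s3y probe set has a suffix that marks cross-hybridisation within a gene family, so its signal may not come from the Y chromosome, and the sex ratio of the pools stays open.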
